A study of Mus musculus with 4 samples.

How the data were processed

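RNA from mouse splenic CD4+ T cells was hybridised to Affymetrix whole-transcript gene arrays, 1 sample per array. The authors deposited linear intensity values made with RMA and Affymetrix Power Tools, per the submitters' processing notes, which give no versions. RMA subtracts background, equalises the arrays' distributions and summarises the probes of each transcript, but which arrays were processed together is not given in the sources used here. The 4 arrays did not share 1 distribution, since their 75th percentiles were 669 and 730 at baseline, 769 at 2 h and 574 at 8 h. Log2 of the deposited intensity was taken here with no pseudocount. RMA values keep some signal from unspecific binding, so the fold of a dim gene is understated.

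The table held 24922 rows. Rows were named through the platform's annotation: 21425 had 1 gene symbol, 1399 had several and 2098 had none listed. Gene identifiers were looked up in a RefSeq gene table of the assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. It changed 0 symbols, and 78 symbols had no match and were kept as given. Rows with several symbols or none were left out of the main analysis. A gene with more than 1 row (921 genes) was represented by the row with the highest mean. Genes were kept when they lay above the array's median of all rows on at least 1 array, which left 10699 and put 9053 aside as dim.

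Samples were grouped by the treatment time in their labels into baseline (2 arrays), IFNa for 2 h (1) and IFNa for 8 h (1). Differences were tested with limma 3.58.1 in R 4.3.3, in a model with a mean for each group, empirical Bayes moderation and Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. The spread came from the 2 baseline arrays alone, with 1 residual degree of freedom per gene and a prior of 7.46 degrees of freedom and an SD of 0.175 on the log2 scale. Standard errors are the moderated ones of this model. The comparisons were 2 h against baseline, 8 h against baseline, 8 h against 2 h and the mean of both times against baseline. Counts of at least 2-fold differences used no test.

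For each of 26 gene lists, the median log2 difference of the measured members was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and called under the 2.5th or over the 97.5th percentile. Of these lists 25 had at least 3 tested members. The list of neutrophil and erythroid markers had only Mpo and Slc4a1, neither called. Limma's camera was run with a preset correlation of 0.01. There 14, 12 and 10 lists passed at 2 h, 8 h and 8 h against 2 h. It was also run with a correlation estimated from the arrays, where no list passed in any comparison (lowest unadjusted p 0.0441, 0.0401 and 0.164). The estimated version rests on 1 residual degree of freedom, from the 2 baseline arrays, so it had little power to pass any list. For antiviral effectors at 2 h the camera adjusted p was 1.43e-32 with the preset correlation and 0.709 with the estimated one. Failure with the estimated correlation is therefore not read as a lack of change. Lists are described by their percentile among random lists, which does not allow for genes that vary together. Chance agreement from the shared baseline was simulated 100 times with unchanged groups. The gene lists, the rule for named genes, the tests and most of the other settings tried were fixed before the data were examined.

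The rule for named genes took, per comparison, the 10 largest rises and 10 largest falls among called genes, for the comparisons with baseline only where the IFNa array lay outside both baseline arrays. It also took up to 4 called members of each list with the largest change (or 2 as values where none was called), and 18 fixed genes, of which 16 were tested and 2 had no row that named them alone. Not all of these are named in the text, and predicted genes and olfactory receptors could be left unnamed.

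The scripts were tested on simulated data with 200 changed genes among 10699. For 2 h against baseline 50.7% of genes changed 2-fold and 100% of those changed 4-fold or 8-fold were recovered, and 6.18% of calls were false. For 8 h against baseline these shares were 53.7%, 100% and 10.1% false, and for 8 h against 2 h 11.9% at 2-fold, 97.0% at 4-fold, 100% at 8-fold and 3.47% false. Of 200 random lists with no shift 5.5% were called. Genes varied independently in that simulation, so its share does not cover lists whose genes vary together. Of the 25 lists, antiviral effectors and the Ifi200 and Schlafen families were called lower in baseline 2 than in baseline 1. MHC class I presentation, immediate early genes, glycolysis and sterol synthesis were called higher in baseline 2.

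Alternatives were quantile normalization, centring each array on its median, no filter or a stricter filter at the 60th percentile, an intensity trend or a robust prior, a 2-fold minimum, an adjusted p under 0.1, the mean of a gene's rows, all rows, 1.5-fold and 3-fold limits, a model with both IFNa arrays as 1 group, and leaving out each array. Chosen after seeing the data were list medians on centred arrays, 3 further gene lists with and without the genes that prompted them, tests of quantile normalized values against the spread of the deposited ones, and the removal from each IFNa array of the part that followed the difference between the baseline arrays, by a slope over all tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genomic coordinates are given because no genome build is named for the arrays in the sources used here.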

Results

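Gene expression was measured in CD4+ T cells from the spleens of 6 week old male C57BL/6 mice, a common inbred strain. The cells had been enriched by negative selection, in which the other cell types are removed, and activated for 48 h with beads that engage CD3 and CD28. They were then cultured with interferon alpha (IFNa) at 100 U/ml, a type I interferon that acts through the receptor chains Ifnar1 and Ifnar2. Of the 4 arrays, 2 held baseline cells without IFNa, 1 held cells after 2 h of IFNa and 1 held cells after 8 h. Nothing in the labels says whether the 2 baseline samples came from separate mice or cultures, so p-values of the model with 3 groups rest on the spread between these 2 arrays, which may be technical. The lone array of each IFNa time was assumed to vary like a baseline array and had no replicate check of its own.

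The deposited intensities ran from 10.3 to 27543, with medians of 195 and 183 on the baseline arrays, 176 at 2 h and 199 at 8 h. The number of arrays limits the precision. Of 19752 genes with a row of their own, 10699 were tested on the log2 scale. Over these genes the baseline arrays correlated at 0.982, the 2 h array with baseline 1 at 0.952 and with baseline 2 at 0.973, the 8 h array with them at 0.952 and 0.939, and the 2 h with the 8 h array at 0.919 (Pearson's r across genes, which are not independent replicates). The baseline arrays differed at least 2-fold in 41 genes. The 2 h difference had a slope of 0.58 on the difference of baseline 2 from baseline 1, and the 8 h difference a slope of −0.36. The median difference of all tested genes was 0.06 at 2 h and −0.16 at 8 h, against −0.01 and 0.00 after quantile normalization and 0.15 and −0.24 with each array centred on its median. Gene lists are therefore described by the percentile of their median among random lists of genes of like expression, and are called when it falls outside the middle 95%.

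The comparison of the 2 h array with baseline asks which genes respond early to IFNa. Antiviral genes were among the 10 largest rises. Rtp4, an interferon-induced antiviral protein, rose 17.6-fold (log2 difference 4.14, SE 0.21, 1 array against 2), from a baseline of 6.47 ± 0.17 (SD, n = 2) on the log2 scale. Ifit3 (3.27, SE 0.22) and Ifit1 (3.0, SE 0.21), which bind viral RNA, and Rsad2 (3.18, SE 0.21), which makes a chain-terminating nucleotide, rose with Oasl2 (3.08, SE 0.21) of the oligoadenylate synthetase family and the dynamin-like GTPase Mx2 (2.95, SE 0.20). Usp18, which restrains signalling from the type I interferon receptor, rose by a log2 difference of 3.22 (SE 0.22), and Irf7, a transcription factor of the interferon response, by 3.15 (SE 0.25). The other large rises were Ifi208 (2.90, SE 0.20) and the ADP-ribosyltransferase Parp12 (2.72, SE 0.20). The adjusted p of these 10 genes ran from 0.000281 for Rtp4 to 0.000902 for Irf7, and each lay above both baseline arrays. Rtp4, Ifit3, Rsad2, Oasl2, Mx2 and Ifi208 were dim at baseline, under the median of all rows on both arrays (mean log2 of 7.56), and Mx2 (4.99) also under the 25th percentile (6.24), so their folds and order rest on dim baseline levels.

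In all, 117 genes rose and 1 fell at 2 h (limma, adjusted p under 0.05). The gene that fell was Abhd18, a predicted hydrolase (−1.21, SE 0.20, adjusted p = 0.0304). After quantile normalization 332 genes were called higher and 109 lower, and all 118 of the calls above were kept, but with the spread of the deposited values, a test chosen after seeing the data, 88 were higher and 2 lower. With no filter on dim rows 84 were higher and none lower, on centred arrays 291 and 7, and with all rows of the array tested limma called none (996 rows at an unadjusted p under 0.05). At least 2-fold differences numbered 189 higher and 7 lower. That total of 196 became 366 without baseline replicate 2 and 144 without baseline replicate 1.

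Of 41 measured antiviral effectors, 18 rose at 2 h and none fell (32 rose when adjusted over the list alone). Their median of 0.92 lay at the 100th percentile (adjusted p = 0.709 with an estimated correlation). The camera test with an estimated correlation rests on 1 residual degree of freedom and had little power, here and for the lists below. Mx1, a gene of the Mx family of GTPases, was among the antiviral effectors that rose (2.58, SE 0.22). Between the 2 baseline arrays this list lay at the 0.105th percentile, lower in baseline 2. Of 32 genes of interferon signalling and nucleic acid sensing, 11 rose (18 adjusted over the list alone), with a median of 0.75 at the 100th percentile (adjusted p = 0.709 with an estimated correlation). They included the RNA sensors Ifih1 (2.43, SE 0.21) and Dhx58 (2.42, SE 0.21) and the signal transducer Stat2 (1.42, SE 0.23). Irf9, the DNA-binding partner of Stat2, stood at 1.04 (SE 0.20, adjusted p = 0.0613) and Irf1 at 0.23 (SE 0.21, adjusted p = 0.68). The receptor genes did not pass, with Ifnar1 at 0.90 (SE 0.22, adjusted p = 0.138) and Ifnar2 at 0.04 (SE 0.20).

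Among 10 guanylate-binding proteins and immunity-related GTPases, which act against intracellular microbes, 4 rose (8 adjusted over the list alone) and the median was 0.94, at the 100th percentile (adjusted p = 0.709 with an estimated correlation). These were Irgm1 (1.62, SE 0.21), Iigp1 (1.51, SE 0.20), Gbp5 (1.42, SE 0.22) and Gbp3 (1.10, SE 0.20). Of 11 listed genes of the Ifi200 and Schlafen families, a list that leaves out Ifi208 and Ifi214, 3 rose (10 adjusted over the list alone), namely Slfn5 (2.35, SE 0.21), Ifi213 (2.28, SE 0.22) and Slfn8 (1.81, SE 0.20). Their median was 0.77, at the 100th percentile (adjusted p = 0.709 with an estimated correlation), and at the 1.74th percentile between the baseline arrays. Of 20 genes of MHC class I antigen presentation only H2-T24 rose (1.49, SE 0.21; 2 adjusted over the list alone). The median of that list was 0.36 (0.21 without baseline replicate 1), at the 100th percentile rounded (adjusted p = 0.792 with an estimated correlation), and it lay at the 99.2th percentile between the baseline arrays. The 8 genes of MHC class II presentation held no call (H2-DMa −0.45, SE 0.22), and their median of −0.10 lay within the range of random lists.

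Immediate early genes, which are transcribed within minutes to hours of a stimulus, were also higher at 2 h. Of 20 measured, 6 rose (12 adjusted over the list alone), among them the stress gene Gadd45b (2.12, SE 0.24), the zinc finger factors Egr2 (1.65, SE 0.21) and Klf10 (1.52, SE 0.20), and Ier5 (1.53, SE 0.23). Their median of 0.93 lay at the 100th percentile (adjusted p = 0.749 with an estimated correlation), and at the 99.2th between the baseline arrays. Of 24 genes of T cell activation and costimulation, 3 rose (6 adjusted over the list alone): the nuclear receptors Nr4a1 (2.30, SE 0.28) and Nr4a3 (1.66, SE 0.20), induced by antigen receptor signalling, and Tnfsf8, the ligand of CD30 (1.28, SE 0.22). Their median was 0.28 (0.44 without baseline replicate 2), at the 99.9th percentile (adjusted p = 0.749 with an estimated correlation). Cd69, an early activation marker, stood at 0.94 (SE 0.20, adjusted p = 0.0862). Among 21 negative regulators of cytokine signalling 3 rose (6 adjusted over the list alone), Usp18, the phosphatase Dusp5 (1.57, SE 0.24) and the PD-1 ligand Pdcd1lg2 (1.14, SE 0.21). The list median was 0.38, at the 100th percentile rounded (adjusted p = 0.749 with an estimated correlation), while Socs1, a Janus kinase inhibitor, stood at 0.27 (SE 0.23, adjusted p = 0.658).

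Of 11 chemokines and cytokines only the chemokine Cxcl10 rose (1.86, SE 0.21; 2 adjusted over the list alone), with a list median of 0.40 (0.63 without baseline replicate 2) at the 99.1th percentile (adjusted p = 0.749 with an estimated correlation). Among 21 genes of apoptosis and cell death, Xaf1, an interferon-induced antagonist of apoptosis inhibitors (2.52, SE 0.20), the death ligand Fasl (1.45, SE 0.20) and Daxx (1.16, SE 0.22) rose (7 adjusted over the list alone). Their median was 0.33 (0.22 without baseline replicate 1), at the 99.9th percentile (adjusted p = 0.749 with an estimated correlation). In 3 further lists the median lay high with no member called over all genes. These were lymphocyte trafficking and quiescence (21 genes, 0.33; Cxcr4 0.97, SE 0.21; 1 adjusted over the list alone; adjusted p = 0.749 with an estimated correlation), S phase (26 genes, 0.31, or 0.19 without baseline replicate 1; Fen1 0.64, SE 0.21; 0 adjusted over the list alone; adjusted p = 0.792 with an estimated correlation) and ribosome biogenesis (25 genes, 0.26; Nop58 0.91, SE 0.25; 0 adjusted over the list alone; adjusted p = 0.792 with an estimated correlation). Mitosis genes lay low, with a median of −0.23 over 23 genes, at the lowest percentile of 0 (Plk1 −0.48, SE 0.21; 0 called over all genes or adjusted over the list alone; adjusted p = 0.709 with an estimated correlation). Helper T cell cytokines (Bcl6 0.89, SE 0.21), heat shock genes (Hsph1 0.87, SE 0.25), glycolysis (Slc2a1 −0.86, SE 0.30), sterol synthesis (Pmvk 0.59, SE 0.25; percentile 2.51, at the edge of the range) and T cell identity genes (Cd247 0.32, SE 0.21) lay within the range of random lists and held no call. Without baseline replicate 1, glycolysis (−0.20, percentile 0.02) and sterol synthesis (−0.25, percentile 0) lay low at 2 h, as they did after removal of the part of each IFNa array that followed the difference between the baseline arrays, an analysis chosen after seeing the data (percentiles 0.01 and 0). Sterol synthesis also lay low after quantile normalization (−0.19, percentile 2.08) and with no filter on dim rows (−0.10, percentile 1.22), and without baseline replicate 2 it stood at 0.06 (percentile 13.8).

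No array of untreated cells kept for the same time was analysed here, so IFNa and time in culture could not be told apart at either time. The preparation note of the IFNa samples also mentions Janus kinase inhibitors as present or absent, while their other labels name IFNa alone.

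**Figure D1:**
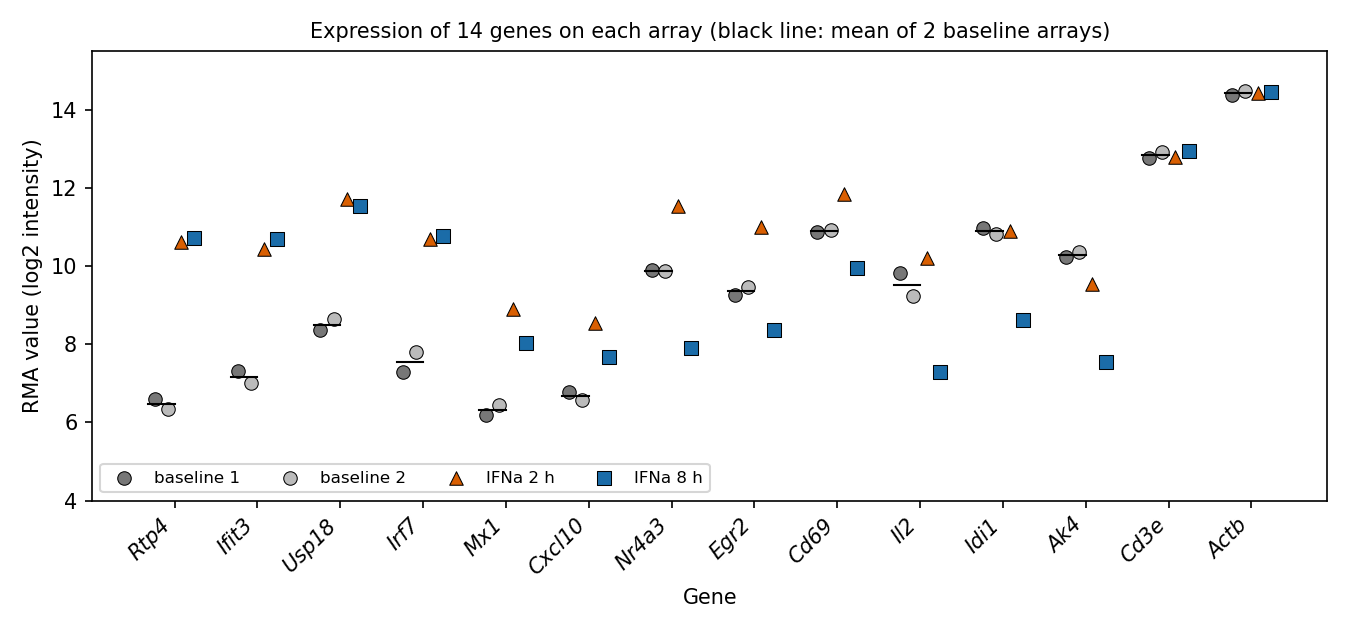
RMA values (log2 intensity, vertical axis) of 14 genes on each of the 4 arrays, with circles for the baseline arrays, a triangle for 2 h and a square for 8 h of IFNa; the black line is the mean of the 2 baseline arrays. Rtp4, Ifit3, Usp18 and Irf7 were higher at both times, Nr4a3, Egr2 and Cd69 lay above baseline at 2 h and below it at 8 h, and Cd3e and Actb differed from baseline by at most 0.09.

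The comparison of the 8 h array with baseline asks which genes are changed later. Interferon-induced genes were high again and sterol synthesis genes fell. Rtp4 (log2 difference 4.24, SE 0.21, 1 array against 2), Ifit3 (3.53, SE 0.22), Irf7 (3.23, SE 0.25), Rsad2 (3.22, SE 0.21), Usp18 (3.02, SE 0.22), Oasl2 (2.95, SE 0.21) and Ifit1 (2.92, SE 0.21) rose. So did 3 members of the Ifi200 family of nucleic acid binding proteins, Ifi208 (3.37, SE 0.20), Ifi214 (3.32, SE 0.20) and Ifi213 (3.09, SE 0.22). The largest falls were the mitochondrial adenylate kinase Ak4 (−2.74, SE 0.20), the fatty acid desaturases Fads2 (−2.53, SE 0.20) and Scd1 (−2.42, SE 0.21), Prelid2 (−2.41, SE 0.21) and the oxygen-sensing prolyl hydroxylase Egln3 (−2.32, SE 0.21). They were followed by the sterol enzymes Idi1 (−2.28, SE 0.21), Lss (−2.21, SE 0.33) and Msmo1 (−2.20, SE 0.21), by Il2, the T cell growth cytokine (−2.23, SE 0.27), and by Socs2, a suppressor of cytokine signalling (−2.18, SE 0.20).

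In all, 70 genes rose and 358 fell at 8 h (limma, adjusted p under 0.05). Adjusted p ran from 0.000232 for Rtp4 to 0.0133 for Lss among the 20 genes just named. After quantile normalization 663 genes were called higher and 900 lower, and all 428 of the calls above were kept, but with the spread of the deposited values 105 were higher and 258 lower. With no filter on dim rows the split was 42 higher and 101 lower, on centred arrays 70 and 724, and with all rows of the array tested limma called none (2367 rows at an unadjusted p under 0.05). At least 2-fold differences numbered 61 higher and 278 lower, and that total of 339 became 528 without baseline replicate 1 and 310 without baseline replicate 2.

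Of the 41 antiviral effectors 25 rose at 8 h and none fell (31 rose when adjusted over the list alone), with a median of 1.02. Mx1 stood among them at 1.71 (SE 0.22). Of the 11 listed genes of the Ifi200 and Schlafen families (Ifi208 and Ifi214 left out), 6 rose (7 adjusted over the list alone), with a median of 1.09, including Ifi209 (1.88, SE 0.20), Slfn8 (1.83, SE 0.20) and Ifi203 (1.60, SE 0.24). Of the 32 genes of interferon signalling and sensing, 11 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.40. Dhx58 (2.71, SE 0.21), the RNA receptor Tlr7 (2.45, SE 0.25), Ddx60 (1.90, SE 0.20) and Irf9 (0.99, SE 0.20) rose, while Stat2 stood at 0.88 (SE 0.23, adjusted p = 0.0725) and Irf1 at −0.53 (SE 0.21, adjusted p = 0.174). All 3 of these lists lay at the 100th percentile (adjusted p = 0.778 with an estimated correlation for each).

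The 10 guanylate-binding proteins and related GTPases held no call at 8 h (2 higher when adjusted over the list alone), with Gbp9 at 0.86 (SE 0.20) and Irgm1 at 0.79 (SE 0.21). Their median was 0.05 (0.09 without baseline replicate 1), at the 99.2th percentile (adjusted p = 0.778 with an estimated correlation), and its sign turned to −0.03 with arrays centred on their medians. That call ended without baseline replicate 2 (percentile 96.3) and after removal of the part of each IFNa array that followed the difference between the baseline arrays (97.4). In MHC class I presentation H2-T24 rose (2.03, SE 0.21; 1 adjusted over the list alone), with a list median of 0.08 at the 99.9th percentile that became 0.00 with arrays centred on their medians, 0.01 without baseline replicate 1 and 0.18 without baseline replicate 2 (adjusted p = 0.778 with an estimated correlation). Of the 21 apoptosis genes Xaf1 rose (2.71, SE 0.20) and Bcl2, a survival factor, fell (−1.12, SE 0.20), with 2 higher and 2 lower adjusted over the list alone. Their median of 0.06 lay at the 99.6th percentile (adjusted p = 0.778 with an estimated correlation), turned to −0.02 with centred arrays, stood at 0.03 without baseline replicate 1, and fell within the range after quantile normalization (96.6), without baseline replicate 2 (0.04, 93.6) and after the removal (92.5).

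Sterol synthesis genes fell together at 8 h. Of 18 measured, 11 fell and none rose (all 18 fell when adjusted over the list alone), with Cyp51 (−2.14, SE 0.20) beside Idi1, Lss and Msmo1. Their median of −1.36 lay at the percentile of 0 (adjusted p = 0.778 with an estimated correlation), and between the baseline arrays the list lay at the 99.7th percentile, higher in baseline 2. Of 17 genes of glycolysis and its regulation, a list wider than the glycolytic enzymes, 4 fell (11 adjusted over the list alone): the mitophagy receptor Bnip3 (−2.06, SE 0.24), hexokinase Hk2 (−1.66, SE 0.25), phosphofructokinase Pfkl (−1.5, SE 0.28) and Tpi1 (−0.99, SE 0.21). The median was −0.89 (−0.57 without baseline replicate 2 and −1.12 without baseline replicate 1), at the percentile of 0 (adjusted p = 0.778 with an estimated correlation), with the baseline arrays at 100 rounded. Of 25 genes of ribosome biogenesis and translation 8 fell (17 adjusted over the list alone), among them the nucleolar protein Nop58 (−1.46, SE 0.25), the RNA polymerase I subunit Polr1b (−1.44, SE 0.21) and the polyamine enzymes Srm (−1.26, SE 0.24) and Odc1 (−1.18, SE 0.20). Their median was −0.83, again at the percentile of 0 (adjusted p = 0.778 with an estimated correlation).

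Of 18 heat shock and unfolded protein response genes 3 fell (7 adjusted over the list alone), asparagine synthetase Asns (−1.63, SE 0.26), the transcription factor Xbp1 (−1.12, SE 0.21) and the chaperonin Hspd1 (−0.97, SE 0.20). The median of −0.39 lay at the 0.22th percentile (adjusted p = 0.778 with an estimated correlation), and at −0.25, the 2.6th, without baseline replicate 2, inside the range. Of 21 negative regulators of cytokine signalling Usp18 rose, and Socs2, Cish (−2.08, SE 0.27) and Socs1 (−1.05, SE 0.23) fell, with 2 higher and 6 lower adjusted over the list alone. Their median of −0.45 lay at the 0.18th percentile (adjusted p = 0.778 with an estimated correlation), and at −0.28, the 5.43th percentile, without baseline replicate 2.

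Activation genes moved in part. Nr4a3 (−1.99, SE 0.20), the transcription factor Irf4 (−1.51, SE 0.24) and Cd69 (−0.95, SE 0.20) were the 3 of 24 activation genes that fell (3 adjusted over the list alone). Of 20 immediate early genes 5 fell (5 adjusted over the list alone), including Nfil3 (−1.46, SE 0.20), Jun (−1.38, SE 0.23), Atf3 (−1.28, SE 0.24) and Myc (−1.20, SE 0.21). Among the 21 helper T cell genes Il2, Il4 (−1.37, SE 0.20) and the interleukin 12 receptor chain Il12rb2 (−1.28, SE 0.20) fell (1 higher and 4 lower adjusted over the list alone). Of 11 chemokines and cytokines Lif (−2.09, SE 0.22), Lta (−1.74, SE 0.20) and Tnf (−1.30, SE 0.23) fell and 2 rose, Cxcl10 (1.01, SE 0.21) among them, with 2 higher and 4 lower adjusted over the list alone. The medians of these 4 lists lay within the range of random lists.

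Trafficking and quiescence genes lay high at 8 h with no call (21 genes, median 0.22, 100th percentile; Il7r 0.68, SE 0.20; 0 adjusted over the list alone; adjusted p = 0.778 with an estimated correlation). T cell identity genes (12 genes, median 0.12, 99.4th percentile; Cd27 0.72, SE 0.20) and MHC class II genes (8 genes, median 0.11, mean −0.03, 99th percentile rounded; H2-DMa −0.56, SE 0.22) also held none, over all genes or adjusted over the list alone (adjusted p = 0.778 with an estimated correlation for both). Without baseline replicate 1 the medians of these last lists became 0.00 (89.8) and −0.05 (94.1), within the range, as was the second after quantile normalization (96.1), and the second stood at 0.19 without baseline replicate 2. S phase (Gins1 −0.85, SE 0.23) and mitosis genes (Bub1b −0.37, SE 0.22) lay within the range with no call. Among 11 reference genes the transferrin receptor Tfrc fell (−1.36, SE 0.22; 2 lower adjusted over the list alone), and Actb stood at 0.02 (SE 0.20).

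**Figure D2:**
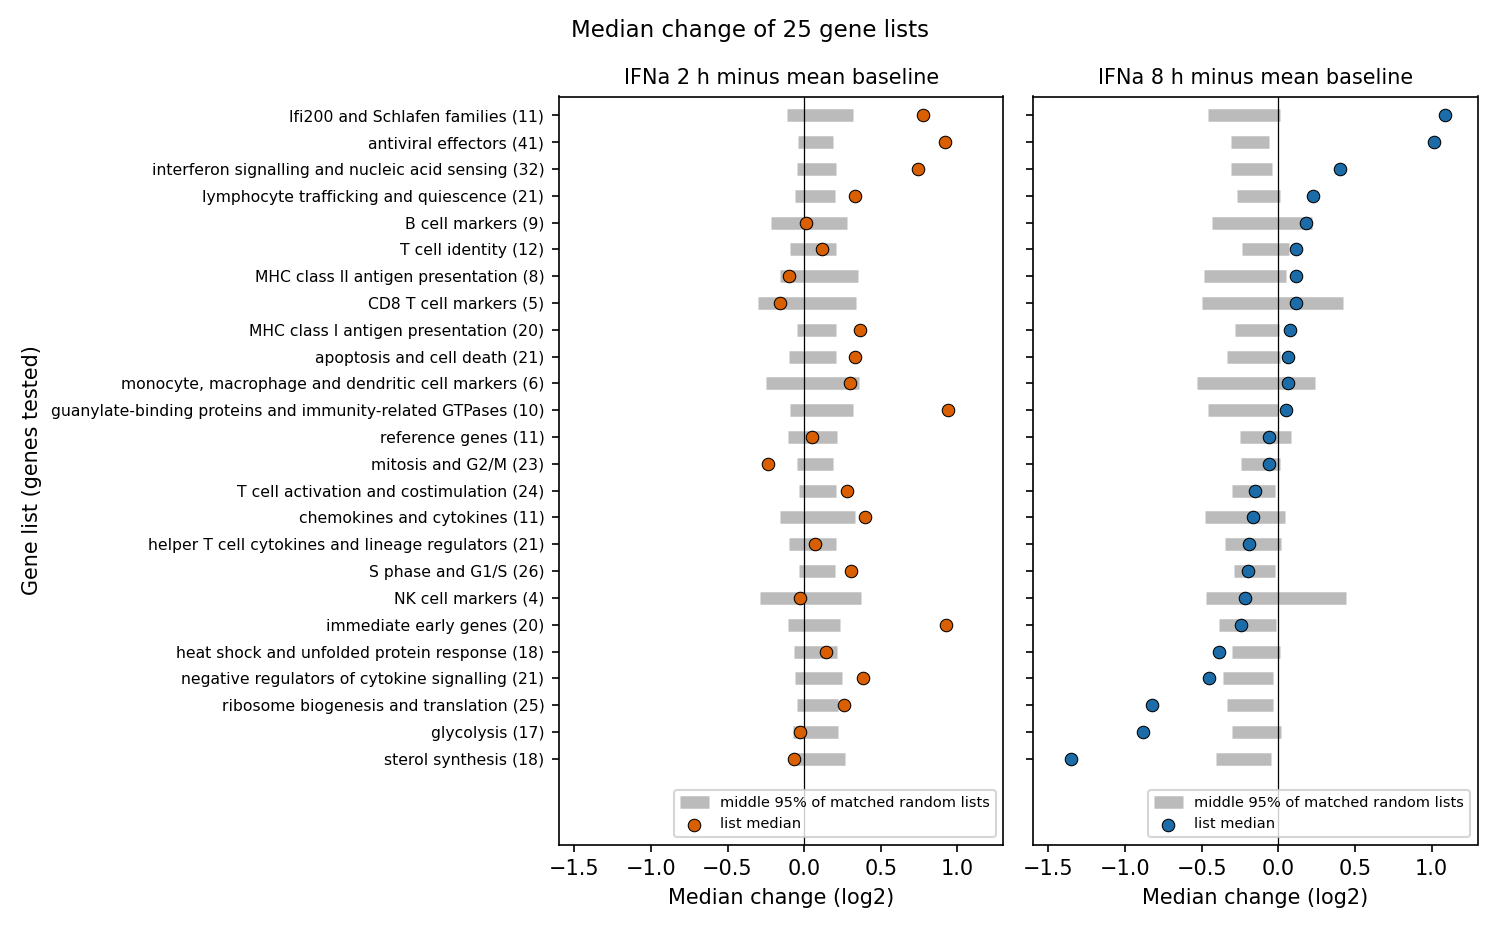
Median log2 difference from the mean of the baseline arrays (horizontal axes) for the 25 gene lists, at 2 h on the left and 8 h on the right, with the number of genes tested in parentheses. Points are list medians and grey bars the middle 95% of 10000 random lists of genes of like expression; sterol synthesis lay at −0.07 at 2 h and −1.36 at 8 h, and antiviral effectors at 0.92 and 1.02.

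Both comparisons were then set side by side. Of the genes that rose, 45 rose at both times, where lists drawn independently would share 0.765 (Fisher's exact test, two-sided, p = 1.86e-74). They included Rtp4, Ifit3, Ifit1, Irf7, Usp18, Rsad2, Oasl2 and Mx1. In simulations of unchanged groups against the same baseline arrays, 0.35 genes on average and at most 3 were called at both times in the same direction, against 46 observed. Abhd18 was the gene that fell at both. A further 4 genes, Nr4a3, Egr2, Ccr8 and Taf4b (the last named after its values were seen), rose at 2 h and fell at 8 h, with 3.91 for independent lists (Fisher's exact test, two-sided, p = 0.798). Across all tested genes the log2 differences of the 2 times correlated at −0.0048, against 0.333 (0.302 to 0.356) in the simulations. The covariance was −7.6e-04, against 0.016 simulated, a difference of −0.017. Genes varied independently in these simulations, while the 2 h and 8 h differences had opposite slopes on the difference between the baseline arrays (0.58 and −0.36). The simulated r and covariance do not cover such array-wide differences, so no conclusion is drawn from the gap. The baseline arrays could not be split into parts of 2, so part of the excess of shared calls may come from the shared baseline. With a separate baseline array for each time, r was −0.245 or 0.105, and 45 or 49 genes changed at least 2-fold in 1 direction at both times, against 46 with the shared baseline (no test).

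**Figure D3:**
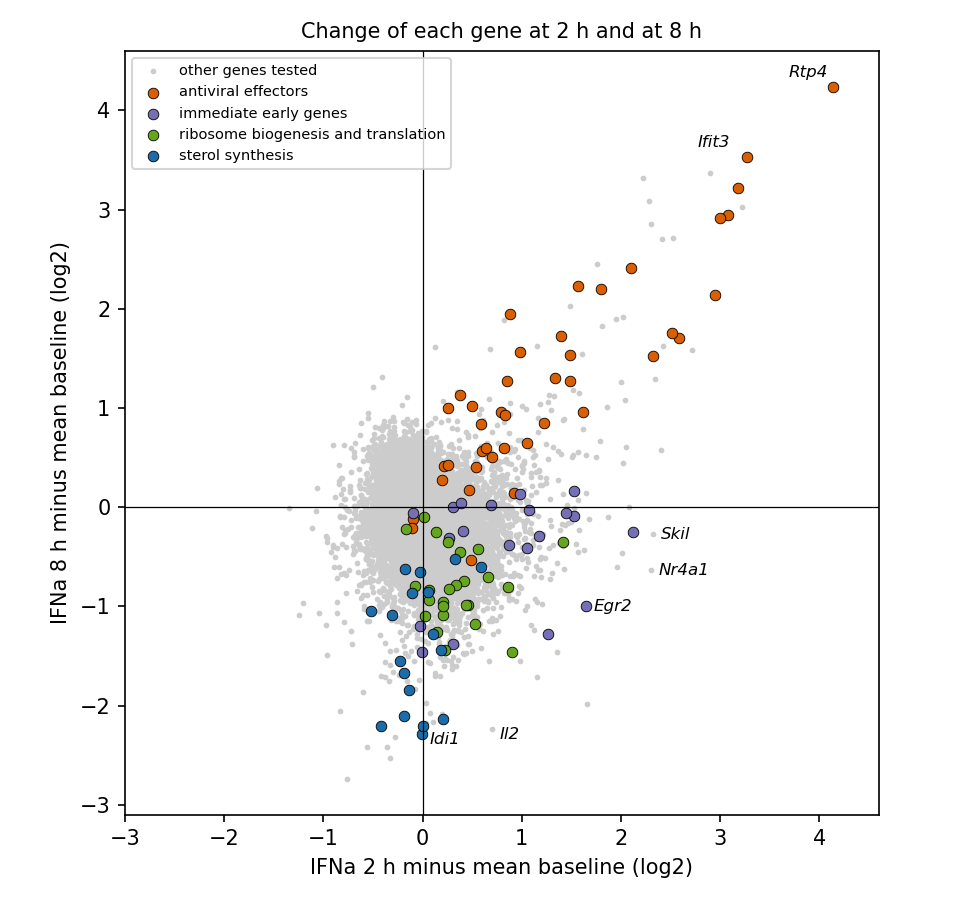
Each point is 1 of 10699 tested genes, with its log2 difference from the mean of the baseline arrays at 2 h (horizontal axis) and at 8 h (vertical axis); coloured points are members of 4 gene lists. Antiviral effectors lie up and to the right, with Rtp4 at 4.14 and 4.24, sterol synthesis genes lie low on the vertical axis, and immediate early genes such as Egr2 (1.65 and −1.0) lie to the right.

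The direct comparison of 8 h with 2 h asks which genes changed between the times. The largest differences were falls. Nr4a3 was lower by a log2 difference of −3.64 (SE 0.23, 1 array against 1), Nr4a1 by −2.94 (SE 0.32), Il2 by −2.93 (SE 0.31) and the transcription factor Bhlhe40 by −2.86 (SE 0.28). The chemokine receptor Ccr8 (−2.82, SE 0.23), Egr2 (−2.64, SE 0.24), the transcriptional repressor Skil (−2.59, SE 0.23), the phosphatase Dusp4 (−2.57, SE 0.26), Atf3 (−2.54, SE 0.27) and the nucleolar protein Nol10 (−2.53, SE 0.29) followed. Several of the most strongly induced interferon genes were not called between the times: Ifit3 stood at 0.26 (SE 0.25), Irf7 at 0.08 (SE 0.29), Ifit1 at −0.08 (SE 0.24) and Usp18 at −0.19 (SE 0.25).

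In all, 156 genes were higher and 1155 lower at 8 h than at 2 h (limma, adjusted p under 0.05), and after quantile normalization 990 and 1316 (214 and 511 with the spread of the deposited values). No filter on dim rows gave 20 and 395, centred arrays 72 and 2315, a 2-fold minimum 70 and 860, and with all rows of the array tested limma called none (3585 rows at an unadjusted p under 0.05). The median difference of all tested genes was −0.25, against 0.00 after quantile normalization and −0.43 with centred arrays. Removal of the part of each IFNa array that followed the difference between the baseline arrays left 31 higher and 429 lower. The largest rises were Prp2 (1.72, SE 0.29), the focal adhesion protein Tns1 (1.53, SE 0.30), Pate11 (1.49, SE 0.24), the synaptic scaffold Shank2 (1.47, SE 0.26), the adhesion molecule Ceacam1 (1.45, SE 0.29), the sialic acid hydroxylase Cmah (1.41, SE 0.24), the defensin Defb46 (1.33, SE 0.33), 2 olfactory receptors and a predicted gene. At least 2-fold differences numbered 80 higher and 925 lower.

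Of the 142 genes that rose at either time, 62 were lower at 8 h than at 2 h, 11 were higher and 69 were not called. Interferon lists here were antiviral effectors, interferon signalling, guanylate-binding proteins, Ifi200 and Schlafen families and MHC class I presentation. In these 5 lists 4 of 49 risen genes were lower at 8 h, against 58 of 93 outside them. Genes outside them included interferon-induced ones such as Usp18 and Ifi208. All 62 came from the 117 genes that rose at 2 h, picked on 1 of the 2 arrays compared, so chance alone favours a lower value at 8 h among them. Of the 358 genes that fell at 8 h, 312 were also lower than at 2 h, where chance likewise favours a lower value, as they were picked on the 8 h array.

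Of the 41 antiviral effectors Herc6 was higher at 8 h (1.07, SE 0.23) and Plscr1 lower (−1.01, SE 0.27; 0 adjusted over the list alone). Their median of −0.03 lay at the 99.7th percentile, turned to 0.26 after quantile normalization, and fell within the range after the removal (95.4; adjusted p = 0.718 with an estimated correlation). Guanylate-binding proteins were lower, with 4 of 10 called (7 adjusted over the list alone) and a median of −0.81 (0.27th percentile; adjusted p = 0.718 with an estimated correlation), among them Gbp5 (−2.05, SE 0.26), Gbp7 (−1.25, SE 0.29), Iigp1 (−1.0, SE 0.23) and Gbp11 (−0.89, SE 0.23). Of the listed Ifi200 and Schlafen genes Ifi209 was higher (1.07, SE 0.23) and Slfn5 lower (−1.06, SE 0.24), with 3 higher and 1 lower adjusted over the list alone and a median within the range. In interferon signalling Irf8 (−1.46, SE 0.24) and Parp12 (−1.13, SE 0.23) were lower (2 adjusted over the list alone), with a median within the range.

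Immediate early genes were lower in 13 of 20 cases (15 adjusted over the list alone), with a median of −1.31 at the percentile of 0 (adjusted p = 0.718 with an estimated correlation), including Gadd45b (−2.37, SE 0.27) and Jun (−1.69, SE 0.27). Ribosome biogenesis genes were lower in 17 of 25 (22 adjusted over the list alone), with a median of −1.16 at the percentile of 0 (adjusted p = 0.718 with an estimated correlation), including Nop58 (−2.37, SE 0.29), Odc1 (−1.71, SE 0.23) and the ribosome assembly factor Rrs1 (−1.67, SE 0.35). Sterol synthesis genes were lower in 11 of 18 (16 adjusted over the list alone), with a median of −1.35 at the percentile of 0 (adjusted p = 0.718 with an estimated correlation), including Cyp51 (−2.34, SE 0.23) and Hmgcs1 (−1.92, SE 0.27). Negative regulators were lower in 11 of 21 (13 adjusted over the list alone), with a median of −0.87 at the percentile of 0 (adjusted p = 0.718 with an estimated correlation), including Socs2 (−2.22, SE 0.23), Cish (−2.15, SE 0.31), Dusp5 (−2.02, SE 0.27) and Dusp6 (−1.77, SE 0.38).

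Heat shock genes were lower in 6 of 18 (9 adjusted over the list alone), with a median of −0.61 at the 0.15th percentile (adjusted p = 0.718 with an estimated correlation) that lay at 2.53, inside the range, with no filter on dim rows. Asns (−1.93, SE 0.30) and the chaperone Hsph1 (−1.74, SE 0.29) were among them. Glycolysis genes were lower in 6 of 17 (6 adjusted over the list alone), Aldoc (−2.22, SE 0.44) among them, with a median of −0.64 at the 0.1th percentile (adjusted p = 0.718 with an estimated correlation) that became −0.25 at 11.2 after the removal. Chemokines and cytokines were lower in 4 of 11 (6 adjusted over the list alone), Lif (−2.28, SE 0.26), Tnf (−1.76, SE 0.26), Lta (−1.71, SE 0.23) and Il15ra (−0.91, SE 0.24). The median of −0.85 lay at the 0.38th percentile (adjusted p = 0.718 with an estimated correlation) and became −0.07 at 3.02 with no filter on dim rows. S phase genes had a median of −0.47 at the 1.13th percentile (adjusted p = 0.771 with an estimated correlation), with Gins1 (−1.25, SE 0.27) and Fen1 (−0.93, SE 0.24) lower (1 adjusted over the list alone). That call ended after quantile normalization (3.56) and after the removal (14.9).

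Activation genes were lower in 7 of 24 (9 adjusted over the list alone), Cd69 (−1.89, SE 0.23) and Tnfsf8 (−1.70, SE 0.25) among them, while their median of −0.45 lay inside the range at the 2.87th percentile and outside it, at 0.11, after the removal (camera, adjusted p = 0.0112 with the preset and 0.718 with an estimated correlation). Apoptosis genes were lower in 5 of 21 (6 adjusted over the list alone), with Fasl (−1.43, SE 0.23) and Bcl2l1 (−1.20, SE 0.28), and helper T cell genes in 4 of 21 (4 adjusted over the list alone), with Il12rb2 (−1.99, SE 0.23) and Il4 (−1.43, SE 0.23), both lists with medians within the range. Mitosis genes (23, median 0.11, 100th percentile rounded) and MHC class II genes (8, median 0.11, 98.5th percentile) lay high with 0 called over all genes or adjusted over the list alone (adjusted p = 0.718 with an estimated correlation for both), and their medians turned to −0.06 and −0.07 with arrays centred on their medians. The second call ended after quantile normalization (94.3). Cd27, a costimulatory receptor, was the T cell identity gene called higher (1.02, SE 0.24; 1 adjusted over the list alone). The median of that list (0.08, 97.0th percentile) lay high with no filter on dim rows (98.4) and after the removal (99.2), and so did trafficking and quiescence genes (−0.02, 96.4th percentile, 0 called over all genes or adjusted over the list alone) after the removal (98.9; adjusted p = 0.718 with an estimated correlation for both lists).

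Averaged over both times, 69 genes were higher and 28 lower than baseline (limma, adjusted p under 0.05), with Rtp4 highest at 4.19. After quantile normalization 215 were higher and 208 lower (73 and 29 with the spread of the deposited values), and with all rows of the array tested limma called none (938 rows at an unadjusted p under 0.05). In a model that took both IFNa arrays as 1 group, 10 genes were higher and none lower, and 186 had an unadjusted p under 0.05.

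Markers of other cell types were examined beside these results. No marker of CD8 T cells (5 genes), NK cells (4), B cells (9) or of monocytes, macrophages and dendritic cells (6) was called in any of the 3 comparisons over all genes; adjusted over the list alone, 1 monocyte marker was higher and 1 lower at 2 h. Lyz2, a macrophage lysozyme, stood at −0.92 at 2 h (SE 0.23), the protease Ctss at 0.78 (SE 0.22), Cd8a at −0.35 (SE 0.23), and the B cell antigen Ms4a1 at 0.75 at 8 h (SE 0.21). All 4 list medians lay within the range of random lists in the 3 comparisons. After quantile normalization CD8 markers lay low at 2 h (−0.24, 2.17th percentile). B cell markers stood at 0.18 at 8 h (95.6th percentile) and lay high after quantile normalization (0.39, 98.7th), without baseline replicate 2 (0.29, 98.8th) and after the removal (0.24, 97.9th). With the preset correlation, camera also called them higher at 8 h than at baseline (adjusted p = 0.0122) and than at 2 h (0.0112), but not with an estimated correlation (0.778 and 0.718). Cd3e, a chain of the T cell receptor complex, stood at −0.04 at 2 h and 0.09 at 8 h, and Cd4 at 0.18 and 0.31.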

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

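The tests for time in culture and for handling were chosen only after the results were seen, as were the removal from each IFNa array of the part that followed the difference between the baseline arrays and the tests of quantile normalized values against the spread of the deposited ones.

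Of the genes named for their difference from baseline at 2 h or 8 h, 60 stood out because that difference was not the same at the 2 times (limma, adjusted p under 0.05 for 8 h against 2 h, 1 array against 1, log2 differences below). Lower at 8 h were transcription factors and early response genes: Nr4a3 (−3.64), Nr4a1 (−2.94), Egr2 (−2.64), Atf3 (−2.54), Gadd45b (−2.37), Jun (−1.69), Irf4 (−1.68), Ier5 (−1.61), Nfil3 (−1.46), Klf10 (−1.36), Myc (−1.17), Bcl6 (−0.96) and Xbp1 (−0.91). Cytokines, receptors and surface proteins were lower too: Il2 (−2.93), Lif (−2.28), Il12rb2 (−1.99), Cd69 (−1.89), Tnf (−1.76), Pdcd1lg2 (−1.74), Lta (−1.71), Tnfsf8 (−1.70), Tfrc (−1.53), Fasl (−1.43) and Il4 (−1.43), as were the survival factor Bcl2 (−0.87) and the signalling regulators Socs2 (−2.22), Cish (−2.15), Dusp5 (−2.02) and Socs1 (−1.32).

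The other genes that stood out are given by function, with no test of these groupings. In lipid synthesis and transfer, genes lower at 8 h were Cyp51 (−2.34), Idi1 (−2.28), Lss (−2.21), Fads2 (−2.20), Prelid2 (−2.06), Scd1 (−1.86), Msmo1 (−1.78) and Pmvk (−1.19). In nucleolar and polyamine metabolism and DNA replication they were Nop58 (−2.37), Odc1 (−1.71), Polr1b (−1.66), Srm (−1.41), Gins1 (−1.25) and Fen1 (−0.93). In energy metabolism and oxygen sensing they were Egln3 (−2.04), Ak4 (−1.98), Hk2 (−1.36), Pfkl (−1.36), Bnip3 (−1.22) and Tpi1 (−0.96), and among stress genes Asns (−1.93), Hsph1 (−1.74), Hspd1 (−1.15) and Hspa5 (−1.0). Of the interferon-induced genes Gbp5 (−2.05), Parp12 (−1.13), Slfn5 (−1.06) and Iigp1 (−1.0) were lower at 8 h, and Ifi214 (1.10) and Ifi209 (1.07) were higher. The costimulatory receptor Cd27 (1.02), a T cell identity gene, was higher too.

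The first pattern weighed is that 358 genes fell at 8 h and 1 at 2 h. A compressed intensity range on the 8 h array is argued against as the whole cause, since after quantile normalization, which made the prior stronger, 100% of these genes passed, and 206 of them (57.5%) passed with the spread of the deposited values, with a median of −1.03 against −1.10 before. After removal of the difference between the baseline arrays 68.2% (244 genes) passed. Genes were called against the spread between these arrays, which favours genes in which they differ little. From such genes the removal takes little, so that share does not decide whether the difference had a part in the falls. The median of all 358 moved from −1.10 (quartiles −1.31 and −0.99) to −1.06 (quartiles −1.27 and −0.95), and of the 114 calls that ended 72 did so because the value shrank past the former p limit and 42 because the limit moved (from 0.00199 to 0.00148). With 0 untreated arrays of the same culture time in the analysis, time in culture without IFNa cannot be told apart from IFNa, so the falls may reflect either the interferon or the time since activation.

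The second pattern is that immediate early genes were higher at 2 h (median 0.93) and lower at 8 h than at 2 h (median −1.31). After removal of the difference between the baseline arrays the list median at 2 h was 0.62 and still lay at the 100th percentile of random lists. The rise was thus larger than the slope over all tested genes gives. A list that follows that difference more steeply would keep a rise, and this list lay at the 99.2th percentile between the baseline arrays. The removal therefore does not decide whether that difference was the whole cause of the rise. Handling or renewed stimulation at the time of IFNa addition cannot be told apart from IFNa, since there were 0 untreated arrays handled alike at 2 h in the analysis. A passing response to IFNa or to handling could each give this course.

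The third pattern is the 156 genes that were higher at 8 h than at 2 h. Of these 7.05% (11 genes) were called as higher at 8 h than baseline. That share does not decide whether most of them rose with IFNa over time, since a rise can go uncalled. In the simulation 53.7% of 2-fold changes were recovered for 8 h against baseline. After quantile normalization, which made the prior stronger, 99.4% (155 genes) passed. Tested against the spread of the deposited values 99 genes (63.5%) passed. Their median grew from 0.98 to 1.13, but the normalization also moved the median of all tested genes from −0.25 to 0.00. That shift favours calls of genes higher at 8 h. These values therefore do not decide whether a compressed range on the 8 h array was the cause. A part in it for compression stays open. Olfactory receptors and keratin-associated genes lay higher at 8 h by medians of 0.36 and 0.56, against 0.12 for all genes with no filter. After quantile normalization they lay higher by 0.09 and 0.23, against 0.02. Compression would give this in such families. However, these families also lay below baseline at 2 h (medians −0.26 and −0.28), and at −0.41 and −0.42 for baseline 2 over baseline 1. The difference between the baseline arrays could thus give these values too. After removal of the difference between the baseline arrays 18.6% (29 genes) passed, as that difference as a cause would give, while the median of the 156 kept most of its size, moving from 0.98 (quartiles 0.92 and 1.10) to 0.84 (quartiles 0.73 and 0.99). Of the 127 calls that ended, 89 did so because the value shrank past the former p limit and 38 because the limit moved (from 0.00612 to 0.00215), so the difference between the baseline arrays cannot be told apart from a change over time, and no biological explanation beyond the 2 times was tested.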

How the results depend on the processing

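The removal of the difference between the baseline arrays, the list medians on centred arrays and the tests of quantile normalized values against the spread of the deposited ones were chosen only after the data were seen.

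Of the total counts recomputed under the alternatives 60 stayed within 1.5 times their reported value and 38 did not. An intensity trend, a robust prior and the mean of a gene's rows left every total they were tried on within that limit, and so did the 2-fold minimum, though with it the genes higher at 8 h than at 2 h went from 156 to 70, and with the trend the falls at 2 h from 1 to 3. No called difference of a named gene changed direction under any of them. Among the named genes 3122 values stayed on their side of the threshold, 311 lost the call and 75 gained it; for list medians these numbers were 369, 17 and 14. Leaving out a baseline array leaves the model with 3 groups no residual degrees of freedom, so only values with no test were computed for it, and 165 named values under each such setting stay within the SD of the baseline arrays by construction, which says nothing about stability. Signal over background limits the 9053 dim genes, which were not tested. No paired analysis was possible because the groups share only replicate number 1.

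After quantile normalization the counts were 441 at 2 h (332 higher, 109 lower), 1563 at 8 h (663, 900), 2306 between the times (990, 1316), 423 on average over both times (215, 208) and 112 shared by both times in 1 direction (95, 17). On centred arrays they were 298 (291, 7), 794 (70, 724), 2387 (72, 2315) and 146 (97, 49). In both settings the prior became stronger, at 34.8 degrees of freedom and without limit against 7.46. Quantile normalized values tested against the spread of the deposited ones gave 725 genes between the times (214, 511), 90 at 2 h (88, 2), 363 at 8 h (105, 258) and 102 on average (73, 29), so the larger counts at 2 h, at 8 h, between the times and on average came with that spread. With no filter on dim rows, which tests 19752 genes, 143 genes were called at 8 h (42, 101), 415 between the times (20, 395) and 59 on average (50, 9), and of the genes reported as called 81 of 117 rises at 2 h, 41 of 70 rises and 100 of 358 falls at 8 h still passed. A stricter filter gave 255 at 8 h (52, 203). An adjusted p under 0.1 gave 188, 1031 and 2999 genes at 2 h, at 8 h and between the times, a rise the looser threshold makes by construction.

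With all rows of the array tested, limma called 0 genes at 2 h, 0 at 8 h, 0 between the times and 0 on average, while 996, 2367, 3585 and 938 of 13781 rows had an unadjusted p under 0.05. The prior fell to 2.99 degrees of freedom there. Rows with several symbols differed at least 4-fold between the baseline arrays in 9.86% of cases (138 of 1399) and rows with no listed gene in 2.76% (58 of 2098), against 0.112% of rows with 1 symbol (24 of 21425). After the removal of the baseline difference 460 genes were called between the times (31, 429) and 604 differed at least 2-fold, with 29 of the 156 rises and 418 of the 1155 falls still called.

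In the model with both IFNa arrays as 1 group 10 genes were called on average (10, 0), where the difference between the 2 times adds to the spread. Leaving out each array in turn in that model gave 15 to 428, with 428 without the 2 h array, 118 without the 8 h array, 15 without baseline replicate 1 and 17 without baseline replicate 2. A 1.5-fold limit gave 890, 1781 and 3732 genes at 2 h, at 8 h and between the times, and a 3-fold limit 50, 69 and 159. Leaving out each baseline array gave 144 to 366 genes changed at least 2-fold at 2 h and 310 to 528 at 8 h, and 14 to 16 and 11 to 12 gene lists called. With a correlation estimated from the arrays, camera called 0 lists at 2 h, 0 at 8 h and 0 between the times, against 14, 12 and 10 with the preset correlation. Its lowest unadjusted p were 0.0441, 0.0401 and 0.164. The estimated version rests on 1 residual degree of freedom and had little power, so this loss of calls does not decide whether the lists changed. Where no cause is stated, the cause was not tested.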

Other observations

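The 3 added gene lists were chosen only after the results were seen, prompted by genes among the falls at 8 h.

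Of 22 measured genes known to be induced by low oxygen through the HIF transcription factors, 9 fell at 8 h (limma, adjusted p under 0.05; 13 adjusted over the list alone), among them Ak4, Egln3, Bnip3, the oxidase Ero1a (−1.45, SE 0.22), Higd1a of the mitochondrial membrane (−1.42, SE 0.20) and the vessel growth factor Vegfa (−1.24, SE 0.21). The list median was −0.87, at the percentile of 0 among random lists, and −0.15 at 2 h, at the 0.2th percentile with 0 genes called (limma; 4 at an unadjusted p under 0.05). The call at 2 h ended without baseline replicate 2 (−0.03, percentile 4.12). Between the baseline arrays the list lay within the range of random lists, at the 81.4th percentile. Of its genes 6 also belong to lists used above, and without them the median was −0.87 at 8 h (percentile 0) and −0.22 at 2 h (percentile 0.05), while between 8 h and 2 h the call of the full list (−0.54, percentile 1.96, 8 genes lower) ended (percentile 5.98), as it did for the full list after the removal of the baseline difference (percentile 5.58).

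Of 13 genes listed for fatty acid synthesis and desaturation 6 fell at 8 h (9 adjusted over the list alone). The list is wider than the enzymes of that pathway, since it includes Tmem97. Beside Fads2 and Scd1 they held Acaca, which makes the precursor malonyl-CoA (−1.75, SE 0.21), Tmem97 (−1.35, SE 0.27), Fads1 (−1.0, SE 0.20) and the synthase Fasn (−0.99, SE 0.22). The list median was −0.94 at 8 h (percentile 0), −0.08 at 2 h, within the range (2.55) but low without baseline replicate 1 (0.07), after the removal (0.06) and with no filter on dim rows (0.63), and −0.70 between 8 h and 2 h (0.375th percentile, 5 genes lower). The list lay at the 99.4th percentile between the baseline arrays. Of 11 amino acid transporters 3 fell at 8 h, the leucine carrier Slc7a5 (−1.59, SE 0.23), Slc6a9 (−1.19, SE 0.20) and Slc7a6 (−1.04, SE 0.21), and 9 adjusted over the list alone. Their median was 0.38 at 2 h (0.20 without baseline replicate 1 and 0.17 after the removal; 99.9th percentile, 0 called by limma, 4 at an unadjusted p under 0.05), −0.71 at 8 h and −1.07 between 8 h and 2 h (both percentile 0, 7 genes lower between the times), and they lay at the 98.0th percentile between the baseline arrays. Without the genes named before or among the 50 largest falls at 8 h, the lists of 17, 10 and 10 genes had medians at 8 h of −0.46 (0.34th percentile, 6 lower), −0.72 (percentile 0, 3 lower) and −0.70 (percentile 0, 2 lower), and at 2 h the first lay within the range (−0.08, percentile 4.59). Between 8 h and 2 h they lay at −0.53 (3.36th percentile, within the range), −0.60 (1.82th) and −1.05 (0). Limma's camera called none of the 3 lists with an estimated correlation (lowest unadjusted p 0.271 at 2 h, 0.175 at 8 h and 0.304 between the times). It called all 3 in each comparison with the preset correlation (highest adjusted p 0.0492). The estimated version rests on 1 residual degree of freedom and had little power. The full lists stayed low at 8 h after quantile normalization (medians −0.70, −0.71 and −0.66), on centred arrays, with no filter on dim rows, after the removal and without either baseline array. The genes named from the added lists were chosen after their values were seen.

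A hypothesis of neighbouring interferon-induced genes was tested on the 142 genes that rose at either time. They formed 18 pairs of neighbours among tested genes, where 10000 random draws gave 1.89 on average and at most 8, which argues against chance placement. Of these, 3 pairs had symbols of different stems (random mean 1.82, at most 8), namely Irgm1 with Gm12185, Rsad2 with Cmpk2 and P2ry14 with Gm9696. The excess may thus come from neighbouring pairs of 1 gene family only, among them the Ifi200 genes and Trim, Oas and Mx pairs.

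Gene families best known from other tissues are given as values, with no test of the families. Of 1027 olfactory receptor genes 32 were tested and 10 called higher at 8 h than at 2 h, and the median of the whole family was 0.36, against 0.09 after quantile normalization and −0.41 for baseline 2 over baseline 1. Medians of 8 h over 2 h were 0.17 for 163 vomeronasal receptors (−0.01 after quantile normalization, 1 tested, 0 called), 0.56 for 62 keratin-associated and cornified envelope genes (0.23 after quantile normalization, 12 tested, 4 called) and 0.39 for 40 beta-defensins (3 tested, 1 called), against 0.12 for all genes with no filter. Among rows outside the main analysis, 0 of 1399 with several symbols and 0 of 2098 with no listed gene lay at least 4-fold above both baseline arrays at both times, against 14 of those with 1 symbol.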
